A study of Bos taurus with 8 samples.

How the data were processed

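Total RNA from blastocysts was extracted with the PicoPure kit, amplified with RiboAmp HS Plus and labelled with Cy3 and Cy5 by the ULS method, per the labels' protocols. The authors deposited 1 scanner table per array, 8 in all, holding the raw spot intensity and local background in Cy3 and Cy5, not background corrected per the file headers; scanner, software and settings are not given in the sources used here. Each table has 43795 probes and 1425 control spots. The authors also deposited a table of processed log2 ratios for the same arrays. Its columns were set against log2 Cy5 over Cy3 of the scanner values for 7668 bright probes: r was 0.956 to 0.976 on the arrays with in vitro in Cy5 and -0.994 to -0.984 on the others, with slopes of 0.915 to 0.941 and -0.984 to -0.974, so the deposited log2 ratios read in vitro over in vivo in every column. Column medians, in the order of replicates 1 to 4, were -0.00385, 0.00131, -0.000779 and -0.00208 with in vitro in Cy5 and 0.00119, 0.000800, -0.00359 and -0.00255 with in vivo in Cy5; how the authors normalized and centred them is not given in the sources used here.

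The labels' numbers 1 to 4 name the replicate, and each number has 1 array per dye orientation. The numbers pair the arrays: deviations from the mean of the own slide correlated across probes at 0.703, 0.894, 0.868 and 0.779 between the 2 arrays of replicates 1 to 4, each higher than with any other number (highest 0.114, -0.476, 0.149 and 0.129). The 2 arrays of a number were therefore averaged as 1 replicate, which also cancels a dye effect, and the test has n = 4. Slide and dye orientation are the same split.

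Foreground means and background medians were corrected with normexp (offset 50) and normalized by loess within each array, control spots at weight 0, in limma 3.58.1 under R 4.3.3; figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Ratios were turned to in vitro over in vivo. The files carry neither an above-background mark nor a background SD in the columns used, so a probe was called detected when its foreground exceeded the 95th percentile of the 153 negative control spots of that channel; 24775 probes (56.6%) detected on all 8 arrays of at least 1 kind of embryo were tested, and 21361 were detected on all arrays in both. The brightest spots per array read 35630 to 40155, and no mark of saturation was used. The test was limma's lmFit on the intercept with eBayes, two-sided, with Benjamini-Hochberg adjusted p under 0.05. With 4 replicates the p-values rest on limma's pooling of the spread over probes (prior df 2.01).

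Gene symbols came from the platform annotation of the array, which can be old: 21790 probes had 1 symbol, 0 had several and 22005 had none, giving 15229 symbols, of which 14114 are current symbols and 1019 synonyms in the ARS-UCD2.0 annotation and 96 are neither. No coordinates are given, since the files name no genome build. Probes without a symbol, 603 of the higher and 872 of the lower probes, were counted and not named. A gene was represented by its brightest tested probe, and gene adjusted p-values were taken over 10188 genes. A probe not above background in 1 kind of embryo has only a bound, and no gene named here was in that case. Some were only a little above it in vivo, where GATM at a log2 level of 6.90 was detected on 6 of 8 arrays. CT47B1 and PSPH were at 7.32, NID2 at 7.28, DDX4 at 7.14 and MAEL at 7.07 in vivo. In vitro, TNP1 was at 7.29, EGR1 at 7.26 and DUSP6 at 7.14. The folds of these and other genes at such levels may be understated.

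Before the data were examined, 29 gene lists, the tests and the rule for naming genes were fixed. The lists cover trophectoderm identity, ruminant trophoblast secreted proteins, pluripotency and inner cell mass, primitive endoderm, sterol biosynthesis and uptake, fatty acid synthesis and desaturation, lipid droplets and fatty acid oxidation, glycolysis and glucose uptake, oxidative phosphorylation, antioxidant and glutathione, metallothioneins, heat shock, unfolded protein and amino acid stress, p53 targets and apoptosis, imprinted genes, chromatin modifiers, interferon response, epithelial junctions, extracellular matrix, cell cycle, ribosomal proteins, growth factors, nutrient transporters, Y-linked and X chromosome genes, and markers of oocytes, cumulus, blood, oviduct and uterus, and sperm. They were tested with limma's camera at a preset correlation of 0.01, beside camera with an estimated correlation and fry, and adjusted over the lists. With an estimated correlation, camera also uses the residual degrees of freedom, here 3. A larger p there need not come from the correlation itself. Named are the 12 largest rises and 12 largest falls among called genes with 1 direction on all 8 arrays and more than a bare locus or clone name (97 called genes had such names), up to 4 called members of each list with the largest change, or all where a list had 5 or fewer, and XIST and DDX3Y. The other genes named beside the list members (INSIG1, IDI1, NSDHL, SQLE, ACAT2, NPC1, SREBF2, INSIG2, FASN, TFAP2C, CDX2, KRT8, IFNT, POU5F1, SOX2, LAMA1, RPS13, PFKFB4, PGAM1, DNAJB9, ASNS, MCM3, MCM4, MCM5, MCM6, MCM7, CENPE, CDK1, RRM2, PCNA, CDC20 and AURKA), and the germ cell and immediate early genes of the closing section (SYCP3, MAEL, TEX11, ASZ1, IER2, DUSP6, EGR1, FOSB, ATF3, KLF6 and NR4A1), were chosen after their values were seen.

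The steps were tested on simulated arrays built from the real intensities and dye effects, with the detection calls of the real arrays over 24775 probes, so the filter itself was not tested. Calls recovered 16 of 67 probes changed 1.5-fold, 48 of 67 changed 2-fold and 65 of 66 changed 4-fold, with 9 calls among 24575 unchanged probes; of 29 simulated lists the 1 that was shifted passed camera and 0 others did. The 9 false calls were 6.52% of all calls. The simulated noise was independent between probes, and its scale was corrected once after a first run. No simulated replicate was made to stand apart, as replicate 2 did in the real data. Far fewer probes were changed than were called in the real data (15.8%). The recovery and the share of false calls therefore need not hold for the real arrays. Alternatives covered background correction, normalization, the deposited log2 ratios, the probe filter, the arrays as replicates (with the replicate block), each dye orientation alone, array weights, thresholds, the mean over a gene's probes and each replicate left out.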

Results

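RNA from expanded bovine blastocysts recovered from the uterus (in vivo) and from blastocysts produced by in vitro maturation, fertilization and culture (in vitro) was hybridised together on 8 two-colour arrays carrying 43795 bovine probes. Collection was on day 7 after insemination and at 168 h after in vitro fertilization, and the treatment text times the uterine flushing at 7.5 days. The labels also record 400 mg FSH in 8 injections, from 60 down to 20 mg, and 500 ug of prostaglandin. They give ablation of follicles from 8 mm, insemination at 12 and 24 h, and aspiration of follicles of 2 to 6 mm. These entries are the same for every replicate, as each array carries both kinds of embryo. An entry that concerns the in vivo or in vitro embryos alone, as FSH treatment or follicle aspiration may, goes wholly with the contrast. The part of such an entry cannot be told apart from in vivo or in vitro origin, and it was not tested. The design names 4 biological replicates of each kind, and each replicate pair was hybridised once in each dye orientation, on slide 58 (in vitro in Cy5) or slide 61 (in vivo in Cy5). The labels do not say how many embryos made up a replicate; they also name the in vitro embryos as OPU embryos in the source name and as coming from slaughterhouse ovaries in the treatment text. Median spot intensity ran from 87.3 to 187 in Cy5 and from 110 to 267 in Cy3, over median local backgrounds of 32 to 42 and 20 to 23. Of all probes, 63.7 to 76.4% per array were detected in the in vitro channel and 60.4 to 83.0% in the in vivo channel. Each log2 ratio below is in vitro over in vivo, as mean ± SE from limma over 4 replicates, with adjusted p from limma.

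The comparison asks which transcripts differ between blastocysts produced in vitro and in vivo. CT47B1, a cancer/testis antigen gene, had the largest rise among named genes, at 3.70 ± 0.35 or 13.0-fold, followed by TRIM63, a muscle ubiquitin ligase, at 2.73 ± 0.11. HMGCS1, CYP51A1, SC4MOL (now MSMO1) and HSD17B7, all enzymes of cholesterol synthesis, rose by 2.55 ± 0.18, 2.53 ± 0.20, 2.44 ± 0.26 and 2.36 ± 0.11. MYL7 (2.43 ± 0.29), TCEAL8 (1.98 ± 0.30), PSPH of serine synthesis (1.94 ± 0.24), TEX12 of the synaptonemal complex (1.92 ± 0.13), the efflux pump ABCB1 (1.90 ± 0.15) and AGXT2L1 (now ETNPPL, 1.86 ± 0.09) made up the 12 largest rises. The 12 largest falls were led by KRT19, a keratin of simple epithelia, at -2.50 ± 0.44, and TDGF1 (now CRIPTO), a Nodal co-receptor, at -2.22 ± 0.24. FOS (-2.00 ± 0.09), the actin-severing SCIN (-1.98 ± 0.20), the trophoblast Kunitz protein gene TKDP1 (-1.85 ± 0.08) and the pluripotency factor NANOG (-1.77 ± 0.13) came next. GIPC2 (-1.70 ± 0.17), CALB1 (-1.67 ± 0.31), the glycolytic enzyme ALDOA (-1.65 ± 0.32), PBXIP1 (-1.65 ± 0.15), CAPG (-1.65 ± 0.26) and PRSS8 (-1.64 ± 0.20) completed the falls. Every one of these 24 genes had its direction on all 8 arrays, with adjusted p between 0.00502 and 0.0260.

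**Figure D1:**
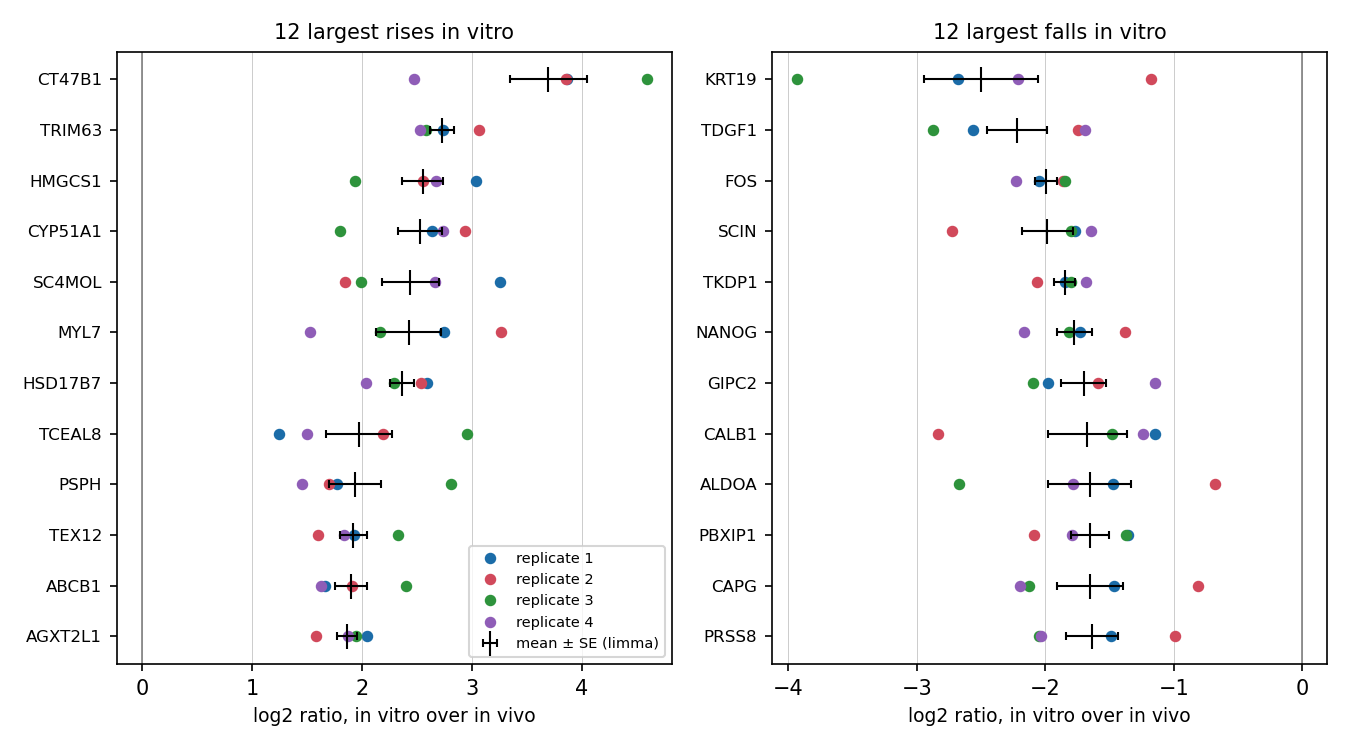
Log2 ratio, in vitro over in vivo, of the 12 named genes with the largest rise (left) and the 12 with the largest fall (right); points are the 4 replicates (each the mean of 2 arrays) and the black bar is the mean ± SE from limma. All 4 replicates of CT47B1 lie between 2.47 and 4.59, and those of KRT19 between -3.93 and -1.18.

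Across the 10188 genes tested, 940 were higher and 1285 lower in vitro at an adjusted p under 0.05; 134 and 192 of them changed at least 2-fold. Called genes were 21.8% of those tested, the share to set beside the list counts below. Among the 24775 probes tested, 1736 were higher and 2181 lower. The median absolute log2 ratio of called genes was 0.61, and 800 of the higher and 1049 of the lower genes kept their direction on all 8 arrays. Another probe of the same gene was called the opposite way in 24 of the 605 called genes with several probes, none of them named here. Other tested probes of FOS, CALB1, TKT, MCM2, DNMT3A and further named genes were not called in either direction. Those calls rest on the brightest probe alone. Replicate 2 stood apart: its ratios correlated across probes at 0.39 to 0.46 with those of replicates 1, 3 and 4, which correlated at 0.80 to 0.82 with each other. Without replicate 2, 1626 genes were higher and 2063 lower, without replicate 1 329 and 468, without replicate 3 372 and 500, and without replicate 4 282 and 357. With the replicate number as a replicate block over all 8 arrays and a dye term, 2678 probes were higher and 3185 lower, and 1377 and 1742 genes. That fit gives every probe the same correlation between the 2 arrays of a replicate (0.834). It takes its degrees of freedom from 8 arrays, though there are 4 replicates, so its added calls are not firmer evidence.

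Of 21 tested genes of sterol biosynthesis and uptake 13 were higher and 1 was lower (15 and 1 when adjusted over the list alone), with a median log2 ratio of 0.88. Beside the 4 enzymes above, the sterol sensor INSIG1 rose by 1.80 ± 0.17, IDI1 by 1.73 ± 0.14, NSDHL by 1.29 ± 0.28, SQLE by 1.27 ± 0.16 and ACAT2 by 1.21 ± 0.20. The member that fell was NPC1, which exports cholesterol from lysosomes, at -0.90 ± 0.16. SREBF2, which encodes the transcription factor of this pathway, gave -0.22 ± 0.18 (adjusted p = 0.460). By limma's camera the list was past the threshold (adjusted p = 1.66e-06); it was not with the correlation estimated from the data (adjusted p = 0.864 with an estimated correlation), and fry gave an adjusted p of 0.0140. The list median was 0.88, 0.71, 0.70 and 0.93 in replicates 1 to 4, and 0.95 on the slide with in vitro in Cy5 and 0.79 on the other.

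**Figure D2:**
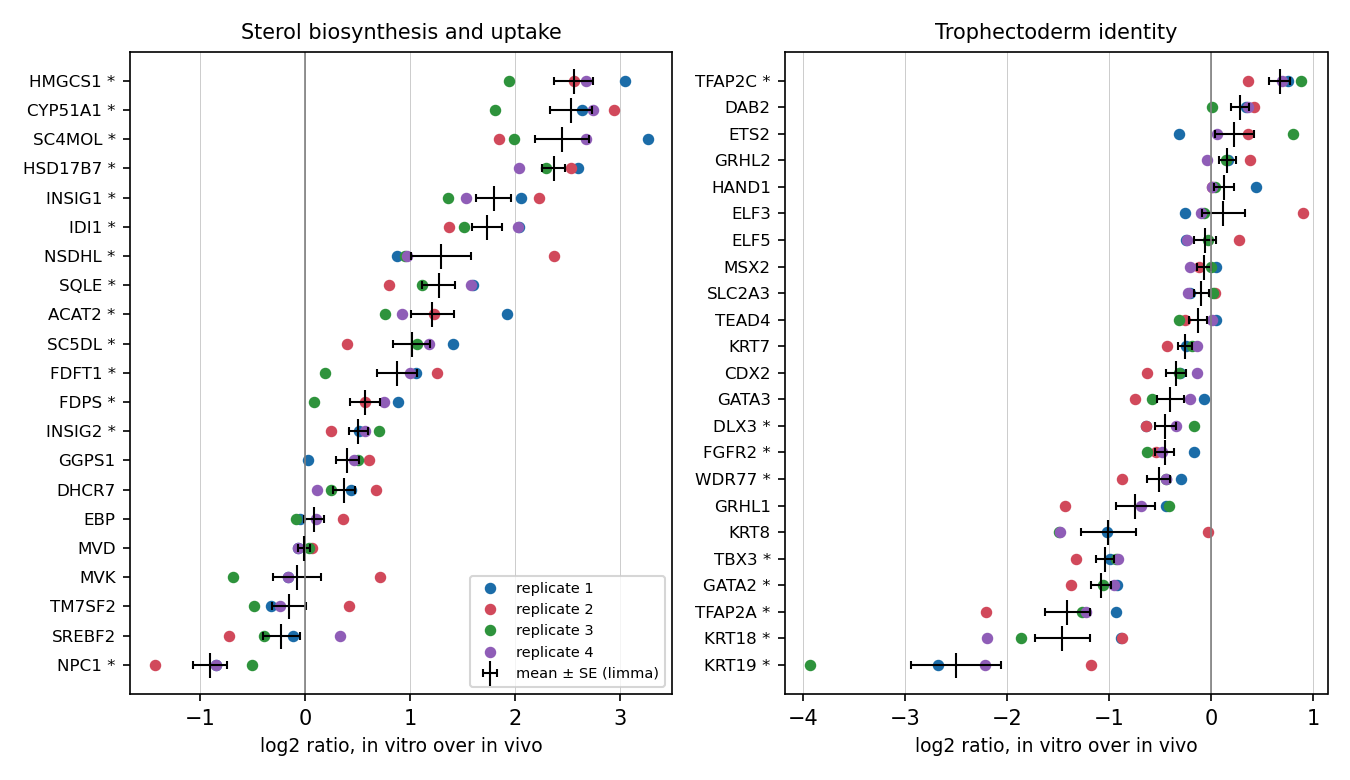
Log2 ratio, in vitro over in vivo, of every tested gene of the sterol list (left) and the trophectoderm list (right); points are the 4 replicates, bars the mean ± SE from limma, and an asterisk marks genes with an adjusted p under 0.05 over all genes. The 13 higher sterol genes lie between 0.51 for INSIG2 and 2.55 for HMGCS1, and KRT19 is the lowest trophectoderm gene at -2.50.

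Among 21 tested genes of fatty acid synthesis and desaturation 5 were higher and 2 lower (6 and 5 when adjusted over the list alone): the desaturase gene SCD rose by 1.77 ± 0.21, ACSL3 by 0.82 ± 0.07, ELOVL6 by 0.76 ± 0.11 and ACLY by 0.64 ± 0.09, while FASN, the fatty acid synthase gene, fell to -0.41 ± 0.10. In lipid droplets and fatty acid oxidation 2 of 28 genes were higher and 5 lower (2 and 6 when adjusted over the list alone). The droplet coat gene PLIN3 (-1.26 ± 0.18) and the electron transfer flavoprotein genes ETFDH (-0.79 ± 0.10) and ETFA (-0.58 ± 0.14) fell, and the dehydrogenase gene ACADM rose by 0.70 ± 0.07.

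Of 23 trophectoderm genes 8 were lower and 1 was higher (13 and 2 when adjusted over the list alone), with a median of -0.35. The keratins KRT19 and KRT18 (-1.46 ± 0.27) and the transcription factors TFAP2A (-1.41 ± 0.22) and GATA2 (-1.08 ± 0.09) had the largest falls, and TFAP2C rose by 0.67 ± 0.10. The master regulator CDX2, detected on 6 of 8 arrays in vitro, gave -0.35 ± 0.09 (adjusted p = 0.0584, and 0.0149 in the replicate block) and KRT8 -1.01 ± 0.27 (adjusted p = 0.0567), neither past the threshold over the 4 replicates. Camera gave the list an adjusted p of 0.0563, and fry gave 0.00893. In the replicate block the pre-ranked form of camera, run on the t-statistics of that fit, gave an adjusted p of 0.0166. The transporter list below also passed there. Both the model and the form of the test differ from the main ones. Camera gave an adjusted p = 0.864 with an estimated correlation, which was 0.0077. The unadjusted camera p rose from 0.0058 to 0.067 there, although this estimate was below the preset 0.01. The trophectoderm call turned on processing: the list also passed with no background correction (adjusted p = 0.0449), with no filter on dim probes (0.0219), without replicate 1 (0.0378) and without replicate 2 (0.0272). Trophoblast secreted proteins had 2 of 17 genes lower and 0 higher (2 and 0 when adjusted over the list alone), TKDP1 and the pregnancy-associated glycoprotein gene PAG2 (-0.88 ± 0.19). The interferon tau gene IFNT gave -0.35 ± 0.23 (adjusted p = 0.358).

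Pluripotency and inner cell mass genes had 2 of 19 lower, NANOG and TDGF1, and 1 higher, the histone variant gene H2AFZ (0.92 ± 0.11); the counts were 2 and 1 when adjusted over the list alone. POU5F1 gave -0.23 ± 0.09 and SOX2 -0.10 ± 0.06, neither past the threshold (adjusted p = 0.155 and 0.266). Of 19 primitive endoderm genes 3 were lower and 4 higher (5 and 4 when adjusted over the list alone). SPARC (-1.31 ± 0.11), HNF4A (-1.02 ± 0.11) and PDGFRA (-0.74 ± 0.09) fell, whereas the basement membrane genes NID2 (1.67 ± 0.11), LAMC1 (0.88 ± 0.20) and LAMA1 (0.85 ± 0.19) rose.

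Of 62 ribosomal protein genes tested 26 were lower and 1, RPS13, was higher (34 and 2 when adjusted over the list alone). The list median was -0.48, and RPS13 had an adjusted p of 0.148 in the replicate block. RPS10 (-1.17 ± 0.25), RPLP1 (-1.17 ± 0.25), RPS12 (-1.14 ± 0.08) and RPS9 (-1.08 ± 0.25) had the largest falls. The list passed camera (adjusted p = 1.72e-07), but not with the correlation estimated at 0.52 (adjusted p = 0.864 with an estimated correlation) nor by fry (adjusted p = 0.0754). The list median was -0.42, -0.68 and -0.60 in replicates 1, 3 and 4 and -0.08 in replicate 2; it was -0.31 on the slide with in vitro in Cy5 and -0.58 on the other.

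Glycolytic and pentose phosphate genes had 8 of 26 members lower and 2 higher (11 and 3 when adjusted over the list alone). ALDOA, the transketolase gene TKT (-1.51 ± 0.13), the enolase gene ENO1 (-1.02 ± 0.17) and PGD (-1.02 ± 0.10) fell, and PFKFB4 (0.67 ± 0.05) and PGAM1 (0.40 ± 0.05) rose. Oxidative phosphorylation had 5 of 73 genes higher and 7 lower (5 and 6 when adjusted over the list alone), with NDUFB2 at 0.66 ± 0.07, NDUFS1 at 0.64 ± 0.08, COX6B1 at -0.66 ± 0.11 and SDHA at -0.65 ± 0.15.

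Stress genes moved both ways, as called genes did over the whole array, and no list in this paragraph passed camera (adjusted p from 0.441 to 0.996). The unfolded protein and amino acid stress list had 5 of 32 genes higher and 5 lower (5 and 6 when adjusted over the list alone). HSP90B1 (-1.46 ± 0.24), PDIA3 (-1.27 ± 0.13) and CALR (-1.17 ± 0.08) fell, whereas PSPH, the co-chaperone gene DNAJB9 (1.09 ± 0.10) and the asparagine synthetase gene ASNS (1.02 ± 0.26) rose. In heat shock and chaperones 4 of 26 genes were higher and 4 lower (4 and 4 when adjusted over the list alone), with HSP90AB1 at -1.25 ± 0.10, HSPA4 at -0.91 ± 0.13, HSPB1 at -0.85 ± 0.20 and HSPB8 at 0.73 ± 0.12. Antioxidant and glutathione genes had 5 of 31 higher and 3 lower (5 and 4 when adjusted over the list alone). GCLM of glutathione synthesis rose by 1.12 ± 0.13, PRDX4 by 0.96 ± 0.12 and NFE2L2, which encodes the NRF2 transcription factor, by 0.88 ± 0.11, and the sulfiredoxin gene SRXN1 fell to -1.12 ± 0.15. Of 5 metallothionein-related genes 1 was lower (1 when adjusted over the list alone), MT1A at -0.72 ± 0.11. HSPB1 and MT1A differed between slides: with in vivo in Cy5 they were 0.37 and 0.44, and with in vitro in Cy5 they were -2.07 and -1.89. Among 24 apoptosis and p53 target genes 3 were higher and 2 lower (4 and 2 when adjusted over the list alone): MCL1 (0.62 ± 0.06), GADD45G (0.50 ± 0.11), PERP (0.37 ± 0.07), DIABLO (-0.68 ± 0.13) and CASP6 (-0.45 ± 0.11).

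Cell cycle and DNA replication genes moved both ways, and camera gave their list an adjusted p of 0.868. Of 46 tested 10 were higher and 14 lower (13 and 15 when adjusted over the list alone). The replication licensing genes MCM2 (-1.37 ± 0.11) and ORC1L (now ORC1, -1.14 ± 0.27) and the cyclin gene CCND2 (-1.37 ± 0.18) fell, as did MCM3, MCM4, MCM5 and MCM7, with log2 ratios between -0.87 and -0.37. The remaining helicase gene, MCM6, gave 0.30 ± 0.11 (adjusted p = 0.123). The spindle checkpoint gene MAD2L1 rose by 1.26 ± 0.20, the kinetochore motor gene CENPE by 0.98 ± 0.14 and the mitotic kinase gene CDK1 by 0.85 ± 0.11. Replication genes also rose, RRM2 by 0.95 ± 0.14 and PCNA by 0.56 ± 0.07, and mitotic genes also fell, CDC20 to -0.85 ± 0.08 and AURKA to -0.62 ± 0.15. DNA methylation and chromatin modifiers had 6 of 30 genes lower and 2 higher (7 and 2 when adjusted over the list alone). The deacetylase genes HDAC8 (-1.57 ± 0.18) and HDAC1 (-0.93 ± 0.14), the demethylase gene KDM1A (-0.79 ± 0.07) and the de novo DNA methyltransferase gene DNMT3A (-0.75 ± 0.11) fell. The DNMT3A probe read up to 36491, within the range of the brightest spots per array (35630 to 40155). Its ratio was -0.31 with in vitro in Cy5 and -1.195 with in vivo in Cy5, so the size of its fall is uncertain. Of 12 imprinted genes 1 was lower, IGF2R (-0.91 ± 0.12), and 1 higher, NDN (0.68 ± 0.15), the same counts as when adjusted over the list alone.

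XIST, the RNA of the inactive X chromosome, gave -1.59 ± 0.55 (adjusted p = 0.107), with replicate values of -3.09, -2.02, 0.30 and -1.56. In the replicate block it passed (adjusted p = 0.0158), and it also passed without replicate 3 (-2.22, adjusted p = 0.0418). The block call has the limit given above, and the other leaves out the replicate that went the other way. The Y-linked DDX3Y gave 0.13 ± 0.07 (adjusted p = 0.272). Its highest reading on any array was 247, where the 95th percentile of the negative controls reached 229. So close to background, its ratio says little about the sex make-up. In the list of Y-linked and X chromosome genes 1 of 13 was higher and 2 lower (1 and 2 when adjusted over the list alone): HPRT1 (1.03 ± 0.09), KDM5C (-0.63 ± 0.08) and CAPG, an autosomal gene that was placed in this list in error.

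Junction genes moved both ways, and camera gave their list an adjusted p of 0.859. Of 32 genes of epithelial junctions and blastocoel formation 4 were higher and 6 lower (4 and 6 when adjusted over the list alone), with the tight junction gene CLDN6 at -1.47 ± 0.12, the desmosomal genes DSP at -0.67 ± 0.09 and DSG2 at 0.91 ± 0.12, and EPCAM at 0.96 ± 0.19. Extracellular matrix and integrin genes had 6 of 31 higher and 3 lower (6 and 5 when adjusted over the list alone): the metalloproteinase inhibitor gene TIMP2 rose by 1.76 ± 0.22, NID2 as above and the collagen gene COL1A2 by 1.34 ± 0.19, and SPARC fell. Growth factor and IGF signalling had 2 of 28 higher and 4 lower (2 and 5 when adjusted over the list alone), with the cytokine gene IL6 at 1.77 ± 0.17 and IGFBP7 at 0.75 ± 0.18 against IGF2R and PDGFRA. Amino acid and nutrient transporters had 7 of 29 higher and 1 lower (9 and 1 when adjusted over the list alone). ABCB1, the neutral amino acid transporter gene SLC1A4 (1.67 ± 0.35), the transferrin receptor gene TFRC (1.49 ± 0.09) and ABCG2 (1.29 ± 0.09) rose. ABCB1 and ABCG2 encode efflux pumps, so the list does not hold nutrient uptake alone. Camera gave that list an adjusted p of 0.104 (adjusted p = 0.864 with an estimated correlation). The camera adjusted p was 0.0290 without replicate 1 and 0.608 without replicate 2. In the replicate block the pre-ranked form of camera gave 0.00686. Of 22 interferon response genes 1 was higher, LGALS3BP (0.83 ± 0.14), and 1 lower, IRF5 (-1.25 ± 0.14), the same counts as when adjusted over the list alone.

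Markers of other cells that a flushed or cultured embryo sample could hold were tested in 5 lists. Maternal and oocyte transcripts had 3 of 19 higher and 0 lower (3 and 0 when adjusted over the list alone): the germ cell helicase gene DDX4 (1.34 ± 0.22), GTSF1 (0.87 ± 0.08) and PTTG1 (0.50 ± 0.06), the last also a cell cycle gene. Of 16 cumulus and granulosa genes 1 was higher and 3 lower (1 and 3 when adjusted over the list alone). The steroidogenic genes HSD3B1 (-1.56 ± 0.23) and STAR (-1.22 ± 0.12) and the inhibin gene INHBB (-0.36 ± 0.09) fell, and GATM, detected on 6 of 8 arrays in vivo, rose by 0.80 ± 0.13. INHBB lost its call in the replicate block (adjusted p = 0.0599). Blood and immune markers had 1 of 13 higher, the lysozyme gene LYZ1 (0.87 ± 0.16), and 0 lower, the same counts as when adjusted over the list alone. Oviduct and uterine epithelium markers had 2 of 18 higher and 5 lower (2 and 5 when adjusted over the list alone). Beside TDGF1, which the pluripotency list also holds, GRP (-0.48 ± 0.08) and MUC1 (-0.45 ± 0.10, detected on 7 of 8 arrays in vitro) fell and CLDN10 (0.48 ± 0.08), a junction gene, rose. Of 8 sperm and spermatid genes 1 was lower (1 when adjusted over the list alone), the transition protein gene TNP1 at -1.63 ± 0.14.

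**Figure D3:**
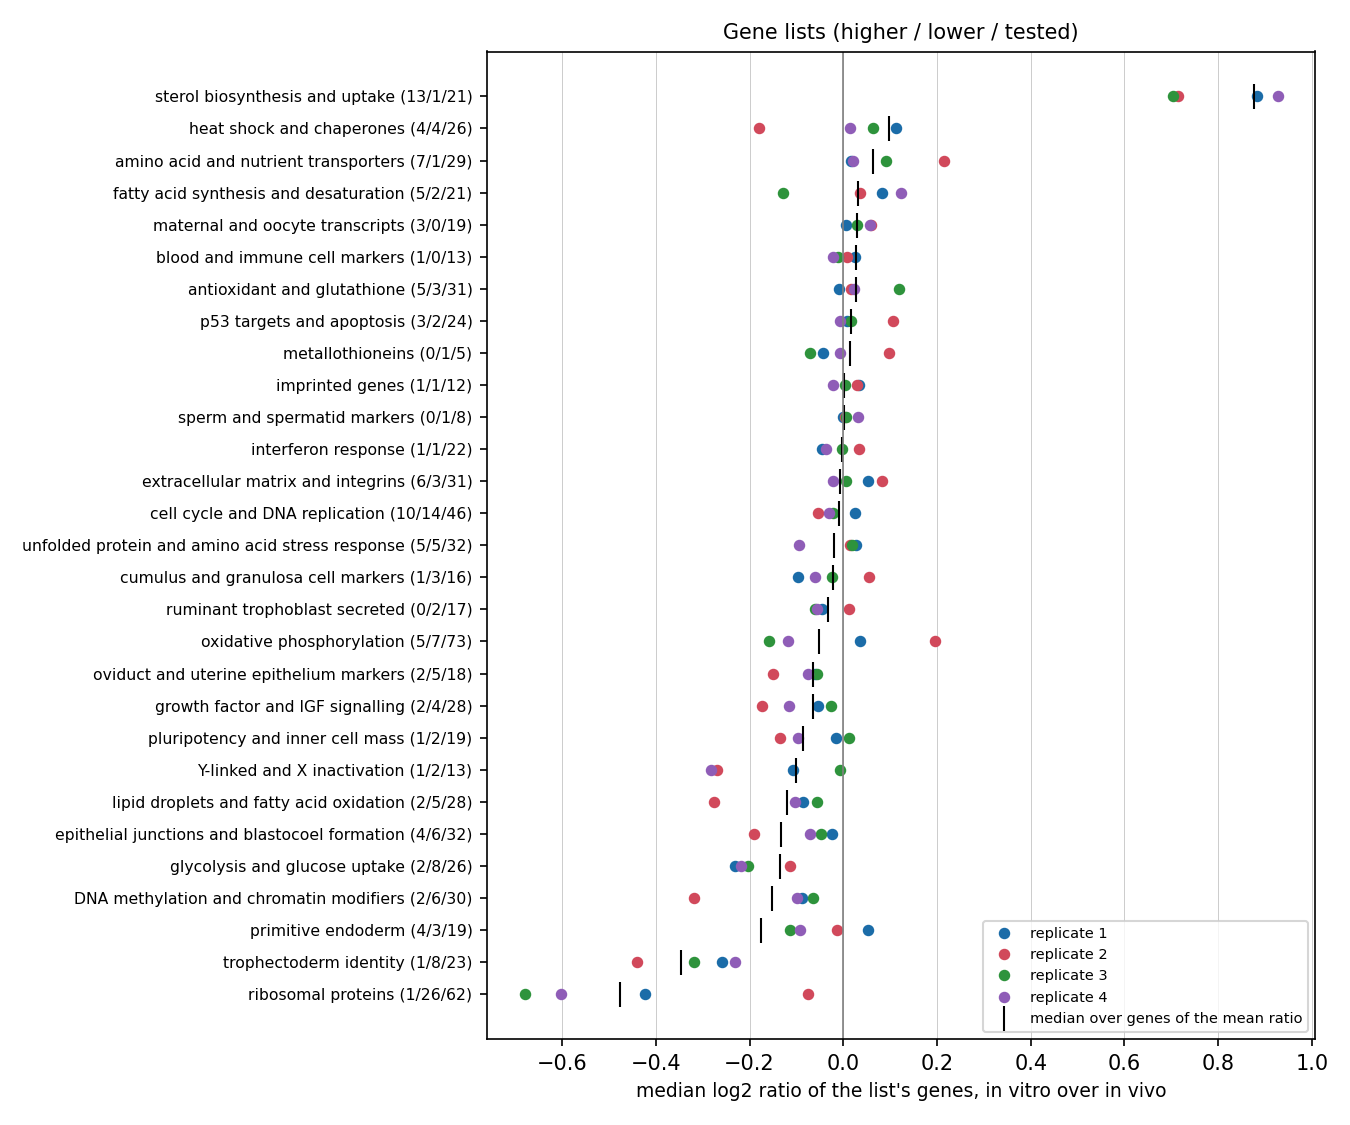
Median log2 ratio, in vitro over in vivo, of each of the 29 gene lists; points are the medians in the 4 replicates, the black bar is the median over genes of the mean ratio, and the numbers in brackets are genes higher, lower and tested. The sterol list lies between 0.70 and 0.93 in all replicates, and the ribosomal list at -0.08 in replicate 2 and between -0.68 and -0.42 in the others.

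Of the 29 lists, 2 passed camera, sterol biosynthesis higher and ribosomal proteins lower; the other lists had adjusted p between 0.0563 and 0.996, and 0 lists passed with an estimated correlation, where sterol biosynthesis had the smallest unadjusted p (0.0353). The replicate block, with the pre-ranked form of camera, put 4 lists past the threshold. By fry, which asks whether a list's genes move on balance one way and does not compare them with other genes, 5 lists passed: trophectoderm identity, trophoblast secreted proteins, sterol biosynthesis, maternal and oocyte transcripts, and oviduct and uterine epithelium markers. The median, mean and test did not share a sign for oxidative phosphorylation, antioxidant, metallothionein, heat shock, imprinted, interferon, extracellular matrix, cell cycle and sperm lists. With the dye term, 16498 probes (66.6% of those tested) differed between the dye orientations, which are also the slides, so dye and slide cannot be told apart; each ratio above averages both.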

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

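The tests of replicate 2, of the sterol list by dye and by replicate, and of short abundant transcripts were chosen only after the values they use had been seen; the tests on intensity, and of dye for the ribosomal list, were not. Of 109 named genes, 29 list medians and 10 array measures, 4 genes, 2 lists and 0 array measures had 1 of 4 values far from the other 3, where chance gives about 1 in 20. ORC1L was at -0.12 in replicate 2 against -1.60 to -1.38 in the others, TKT at -1.03 in replicate 2 against -1.71 to -1.64, and SCIN at -2.73 in replicate 2 against -1.80 to -1.65. PERP was at 0.55 in replicate 4 against 0.29 to 0.33. The median of the chromatin modifier list was -0.32 in replicate 2 against -0.10 to -0.07, and that of the unfolded protein and amino acid stress list -0.095 in replicate 4 against 0.01 to 0.03. The ratio of 16498 probes differed between the dye orientations by the dye term of the 8-array fit.

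Replicate 2 stood apart from the other 3 across probes, and 4 of the 6 single values above are its own. A fault on 1 array is argued against, since its 2 arrays, on different slides and in opposite dyes, deviated together (r = 0.894 across probes). A weaker signal is argued against too: its lowest share of detected probes was 66.0%, above the lowest of the others (60.4%). A different sex make-up cannot be told apart: XIST was at -2.02 in replicate 2, and the others were too far apart (-3.09 to 0.30) to set a range. A difference between embryo pools or in RNA amplification stays open, as no label separates this replicate.

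The rise of sterol genes was set against 3 technical explanations. Dye bias is argued against by the lower of the medians of the 2 orientations, 0.79. Background correction of dim spots is argued against by the list median with no background correction, 0.87 against 0.88 with it. The brighter members had a median of 1.28 and the dimmer ones 0.37. That split cannot decide, as intensity was averaged over both channels and a rise in vitro itself makes a gene brighter. Replicate 2 did not carry it, as the lowest median of replicates 1, 3 and 4 was 0.70. A candidate explanation, untested here, is that embryos in culture may sense less sterol than embryos in the uterus, since the medium and the uterus differ with the design; adding cholesterol to the medium and measuring HMGCS1 would test it.

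The lower ratios of ribosomal protein genes went beyond a trend with spot intensity: the list median of -0.48 was at the 0.01 percentile, the smallest possible, of 10000 random lists of the same intensity, whose lowest median was -0.21. The smallest intensity bin held 10 other genes to draw from, so draws there overlapped heavily. The random lists also lack the correlation of the ribosomal genes, estimated at 0.52. The percentile therefore bears on the intensity trend and not on chance. Dye bias is argued against by the higher of the medians of the 2 orientations, -0.31. Unequal loss or amplification of short abundant transcripts cannot be told apart from a change in the embryos: the oxidative phosphorylation genes had a median of -0.051 and a lower quartile of -0.26, above the ribosomal median, but their medians followed the same order over the 4 replicates. In vivo or in vitro origin stays open as the biological explanation.

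Exchanging in vitro and in vivo within replicates gives 8 assignments, too few for a share under 0.05. The real one called 3917 probes and 2225 genes, and 1 of the 8, the real one, called as many; the highest of the others was 0 for both. For lists past camera the real assignment gave 2, 4 of the 8 gave as many, and the highest of the others was 3.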

How the results depend on the processing

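All alternatives were chosen before the data were examined. The 4 counts stayed within 1.5 times under other background corrections, median centring, the deposited log2 ratios, both probe filters and the mean over probes (genes), and Aquantile left every ratio as it was. Treating 8 arrays as independent with a dye term gave 3628 higher and 4493 lower probes and 1738 and 2344 genes; without the dye term it gave 2838, 3425 and 1438 higher genes. These count each RNA pair as more than 1 sample. The replicate block allows for the pairing only through 1 correlation shared by all probes. The replicate block gave 2678 higher probes and 4 lists, and changed the call of XIST and INHBB among the 109 genes named by the fixed rule, and of CDX2, RPS13, ASZ1 and FOSB among the 43 others. Only the arrays with in vivo in Cy5 gave 3195 higher probes; only those with in vitro in Cy5 gave 3064 higher and 3855 lower probes and 1491 higher genes. Array weights, which set replicate 2 at 0.199, gave 3664, 4329, 1757 and 2348. A fold of at least 1.5 gave 943, 1273, 484 and 697, and an adjusted p under 0.01 gave 350, 439, 287 and 379. Leaving out 1 replicate gave 211 to 3300 higher and 276 to 3890 lower probes, 282 to 1626 and 357 to 2063 genes, each highest without replicate 2 and lowest without replicate 4, and 2 to 4 lists. Estimated correlation left 0 lists and fry 5. HSPB1 (0.37) and MT1A (0.44) reversed with in vivo in Cy5 alone, through the dye or slide effect; of 2069 other-setting values of the 109 genes 1883 kept direction and side of the threshold and 180 lost the call, mostly with 3 replicates. The cause of the other changes was not tested.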

Other observations

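Several germ cell genes were among the larger changes, a group gathered after the values were seen. Beside CT47B1 and TEX12, the synaptonemal complex gene SYCP3 was higher in vitro by 1.45 ± 0.12, MAEL of the piRNA pathway by 1.60 ± 0.08, DDX4 by 1.34 ± 0.22 and the meiosis gene TEX11 by 1.20 ± 0.29, each on all 8 arrays (n = 4). The spermatid gene TNP1 went the other way, at -1.63 ± 0.14. That germline genes as a class may be higher in vitro was then tested on 52 further germline genes whose values had not been seen, of which 17 were tested on the arrays. The test gave no support: 0 of them were higher and 0 lower, with a median of 0.03 and a camera p of 0.295. Several were near background in both kinds of embryo, where a small change would be hidden. Log2 levels in vitro and in vivo were 6.94 and 6.95 for TEX101, 7.04 and 7.05 for DMC1, and 6.93 and 6.94 for BRDT. TDRKH was detected in vivo on 3 of 8 arrays. Others were brighter, such as PSMC3IP at 10.81 and 10.74. ASZ1 had the largest value among them, at 0.98 ± 0.35, with -0.28 in replicate 2 and 1.02 to 1.74 in the others (adjusted p = 0.113, and 0.0186 in the replicate block).

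Immediate early genes, also gathered after FOS was seen, leaned to the in vivo side. Of 19 tested 5 were lower in vitro and 0 higher: FOS, IER2 (-1.50 ± 0.17), DUSP6 (-0.89 ± 0.09), EGR1 (-0.66 ± 0.07) and FOSB (-0.65 ± 0.16, adjusted p = 0.107 in the replicate block). ATF3 (0.06 ± 0.08), KLF6 (-0.07 ± 0.07) and NR4A1 (-0.04 ± 0.17) were near 0. The group median was -0.37, with a camera p of 0.00227, or 0.130 with an estimated correlation; both are not independent evidence, as the group was chosen on these values. Flushing and handling of the embryos differed with the groups, and this was not tested.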
